A study of Homo sapiens with 8 samples.

How the data were processed

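RNA was measured on 8 Illumina HumanRef bead arrays, 2 for each of 4 groups. The groups were MDA-MB-231 cells, a breast adenocarcinoma line, and HT1080 cells, a fibrosarcoma line, each given either a scrambled control siRNA or an siRNA against VRK1. All siVRK1 arrays used 1 siRNA sequence, numbered 308 in the labels. Per the labels' protocols, cells grew for 24 h in medium with 10% fetal bovine serum before the siRNA was added with a lipid reagent, and RNA was taken 42 h later, checked for quality and labelled as biotinylated cRNA. The replicate numbers 1 and 2 are those of the labels, which do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

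The deposited table holds 1 log2 intensity per probe and array for 24526 probes, with no missing values and no detection p. Per the submitters' processing notes, GenomeStudio was used, with no version or normalization step named. The columns shared nearly the same distribution when received, with a largest difference between arrays of 0.00232 log2 over the percentiles compared, so the deposited log2 values were used without further normalization. Each array had a median of 5.93 log2. No background value was given in the sources used here, so the intensities were taken to hold an undivided background, which makes log2 changes of dim probes smaller than the true ones. The number of arrays limits the precision.

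Gene names came from the platform annotation supplied with the data and were updated through a table of human genes of the assembly GRCh38.p14, used for names alone. Of the probes, 21834 had 1 gene symbol, 0 had several and 2692 had none. The symbols of 21813 probes were found in the table. No genome build is given in the sources used here and no coordinates were used.

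Probes whose highest group mean lay at or above the median over all probes, 6.08 log2, were kept. This left 12263 probes, of which 1103 had no name. For each gene the kept probe with the highest mean over all arrays stood for it, giving 9451 genes tested. Levels near 5.6 to 6.1 log2 are called background level here.

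Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean per group over all 8 arrays, which leaves 4 residual degrees of freedom and a prior worth 5.86. All 4 groups share 1 estimate of the spread per gene. The comparisons were siVRK1 against control in MDA-MB-231, the same in HT1080, the average of both changes, the difference between them (HT1080 minus MDA-MB-231), and HT1080 control against MDA-MB-231 control. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with calls at an adjusted p under 0.05. Every adjusted p for a gene comes from limma. Standard errors (SE) are those of the limma fit and SD is the standard deviation of the 2 arrays of a group.

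The groups, comparisons, tests, probe rule, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. By that rule VRK1 came first. For each knockdown comparison it then named up to 10 genes with the largest rise and 10 with the largest fall among those called, provided that the siVRK1 arrays all lay beyond the control arrays of the same line. Where fewer than 3 genes passed in a direction it added the 5 with the smallest unadjusted p, named as not past the threshold. For the difference between lines it named 5 in each direction without the condition on single arrays, and for the control-treated lines 10 in each direction. Of the 10 higher in HT1080, 9 are named. No other kept probe of a named gene was called in the opposite direction, but for some genes the other probes changed far less. For each gene list it named the 2 highest and the 2 lowest members in each line. Other genes in the text are called members of these lists or genes called in both lines, and they were chosen after their values were seen.

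Gene sets were 33 lists of 885 symbols in all, 72 of which matched no named probe. They covered the VRK kinases and VRK1 partners, the cell cycle, stress and signalling targets, adhesion and matrix, metabolism, and markers of other cell types. Each list was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The tests were repeated with an estimated correlation and with fry, a rotation test of whether a list's genes move, on balance, one way. Counts of called members are given over all genes tested and adjusted over the list alone.

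The procedure was tested on simulated data with 9451 genes, built like the MDA-MB-231 comparison, over 20 runs with 200 changed genes each. Of changes of 0.5 log2, 27.1% were recovered, of 1 log2 94.6% and of 1.5 log2 99.0%, and 4.92% of calls were false. These shares belong to simulated arrays with a common spread per gene in both lines and independent genes. The real replicates differed more in MDA-MB-231 than in HT1080. The simulation therefore cannot give the share of false calls among the real MDA-MB-231 calls. In a simulated HT1080 comparison of independent genes, a list shifted by 0.4 log2 was called in 20 of 20 runs and 0 of 640 unshifted lists were called.

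The alternatives were quantile normalization, median centring, no filter and a filter at the 75th percentile, the mean of a gene's probes, each kept probe on its own, an intensity trend, a robust prior, a fit of only the groups compared, calls limited to a fold of at least 1.5, a block for the replicate number, and leaving out each array in turn. A background subtraction and array weights per cell line were added after seeing the data. The subtraction took each array's lower quartile as background on the linear scale and added a fixed offset before log2. For dim probes the offset makes changes smaller than plain subtraction would. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.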

Results

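The series asked which genes depend on VRK1, a nuclear serine/threonine kinase that phosphorylates chromatin and nuclear envelope proteins, in 2 cancer cell lines. The data were 8 arrays in 4 groups of 2, siVRK1 and control siRNA in MDA-MB-231 breast adenocarcinoma cells and in HT1080 fibrosarcoma cells. Replicate arrays correlated across probes with r from 0.987 to 0.994. Between 10791 and 10801 probes per array lay above the filter level, a near-equal count that follows from the columns' nearly shared distribution. Replicates differed more in MDA-MB-231 than in HT1080. The SD of the difference between the replicates over genes was 0.269 log2 for control and 0.239 for siVRK1 in MDA-MB-231, against 0.175 and 0.181 in HT1080.

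VRK1 mRNA fell in both lines. In MDA-MB-231 its probe read 7.93 and 7.61 log2 on the control arrays and 6.23 and 6.74 on the siVRK1 arrays. In HT1080 it read 7.84 and 7.88 on the control arrays and 6.57 and 6.51 on the siVRK1 arrays. The change was -1.28 log2 (SE 0.17, limma adjusted p = 0.0117) in MDA-MB-231, which left 41.1% of the control signal, and -1.32 log2 (SE 0.17, adjusted p = 0.0240) in HT1080, which left 40.1%. The difference between the lines was -0.03 log2 (SE 0.24, adjusted p = 0.993). Over both lines VRK1 changed by -1.30 log2 (SE 0.12, adjusted p = 0.000844). These values hold background signal, so the share left in each line may be lower than given. With background subtracted and an offset added before log2, VRK1 changed by -1.81 log2 in MDA-MB-231 (limma adjusted p = 0.0510) and -1.80 in HT1080 (adjusted p = 0.0513). It was called in neither line, and the offset makes both changes smaller than plain subtraction would. With the MDA-MB-231 arrays fitted alone the limma adjusted p was 0.292. The related kinases VRK2 (0.04 in MDA-MB-231, 0.25 in HT1080) and VRK3 (-0.20 and 0.02) were not called. The direction held without each array, and so did the call on the average. In MDA-MB-231 the adjusted p was 0.0518 without HT1080 control 1 or 2. In HT1080 it was 0.304 without control 1, 0.338 without control 2, 0.284 without siVRK1 1 and 0.268 without siVRK1 2, with changes from -1.35 to -1.29 log2.

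**Figure D1:**
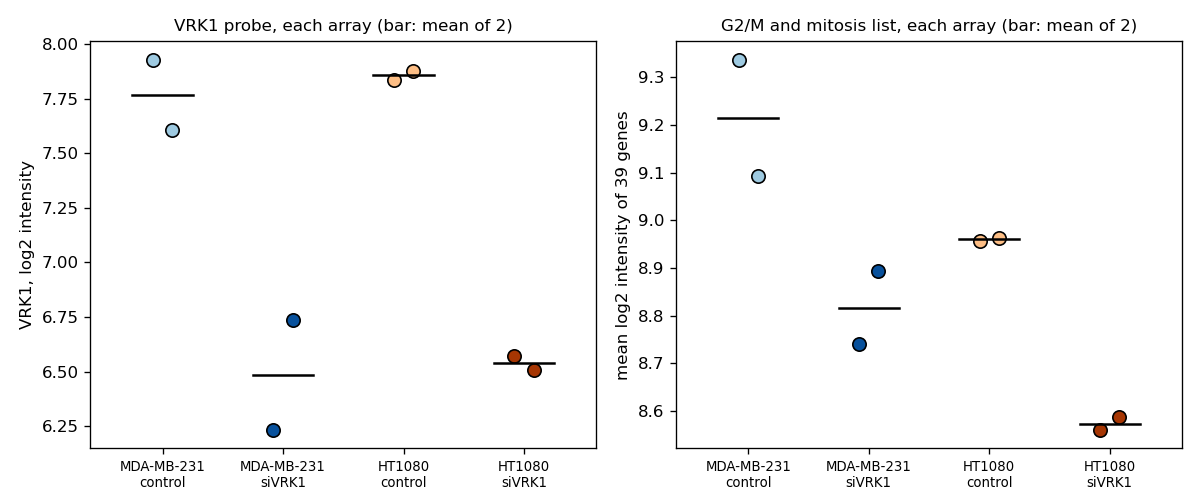
Log2 intensity of the VRK1 probe (left) and mean log2 intensity of the 39 measured G2/M and mitosis genes (right) on each array, with 1 point per array and a bar at the mean of 2. VRK1 lay between 7.61 and 7.93 on control arrays and between 6.23 and 6.74 on siVRK1 arrays, and the G2/M mean was lower on each siVRK1 array than on the control arrays of its line.

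In MDA-MB-231, siVRK1 changed 94 of 9451 genes, 45 up and 49 down (limma, adjusted p under 0.05), with 1244 genes at an unadjusted p under 0.05. The largest rises were in CNN2, an actin-binding calponin, by 1.42 log2 (SE 0.12, adjusted p = 0.00165), ID3, an inhibitor of helix-loop-helix transcription factors, by 1.38 (adjusted p = 0.0234), and TCFL5, a helix-loop-helix transcription factor, by 1.18 (adjusted p = 0.00289). PLLP, a membrane proteolipid, rose by 1.15, TCN1, a vitamin B12 carrier, by 1.09, and FOXN3, a forkhead repressor, by 1.07. CST1, a cysteine protease inhibitor, LRP8, a lipoprotein receptor, P4HA1, a collagen prolyl hydroxylase, and JAG1, a Notch ligand, rose by 0.94, 0.93, 0.91 and 0.88.

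The largest falls in MDA-MB-231 were in SLC2A3, the glucose transporter GLUT3 (-1.76 log2, SE 0.20, adjusted p = 0.00799), IL11, a cytokine of the IL-6 family (-1.61, SE 0.12, adjusted p = 0.00122), and CCNA1, cyclin A1 (-1.44, SE 0.12, adjusted p = 0.00122). IL11 went from 7.61 (SD 0.05) to 5.99 (SD 0.01, n = 2), which is background level, so its fall may be larger than measured. OSTC, a subunit of the oligosaccharyltransferase, changed by -1.25, SFXN1, a mitochondrial serine transporter, by -1.24, PTBP3, an RNA-binding protein, by -1.21 and LCOR, a nuclear receptor corepressor, by -1.18. CENPK, a kinetochore protein, changed by -1.17 and TMEM71 by -1.16. CNN2, TCFL5, SLC2A3, IL11, CCNA1 and CENPK stayed called without each of the 8 arrays, while the other genes named here lost the call without at least 1. FOXN3 and PLLP lost it without 1 (adjusted p up to 0.0547), PTBP3 without 2 and LCOR without 3 (up to 0.0595), LRP8 without 4 (up to 0.0620), ID3 and SFXN1 without 5 (up to 0.100), TCN1, CST1 and TMEM71 without 6 (up to 0.0942), and P4HA1, JAG1 and OSTC without 7 (up to 0.122, 0.0900 and 0.183). The other kept probe of CNN2 read 0.71 and that of LRP8 0.11, and with the mean of its probes LRP8 was not called (0.52, adjusted p = 0.0939). OSTC was not called with the mean of a gene's probes, with a robust prior or with no filter, and P4HA1 was not called with no filter. The count was 59 without MDA-MB-231 control 1, 16 without MDA-MB-231 siVRK1 1, 10 without HT1080 control 1 or 2, and 24 without HT1080 siVRK1 1 or 2. It was 0 with the MDA-MB-231 arrays fitted alone, so the calls rest on a spread shared with the HT1080 arrays. Leaving out an HT1080 array alters only the estimate of that spread, and the changes in MDA-MB-231 stay as they were. With a replicate block the count was 297, with background subtracted 8 and with array weights per cell line 51.

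In HT1080, siVRK1 changed 29 genes, 8 up and 21 down, with 981 at an unadjusted p under 0.05. The rises were in FOXN3 (0.96 log2, SE 0.13, adjusted p = 0.0240), HAS3, a hyaluronan synthase (0.93, SE 0.11, adjusted p = 0.0240), CNN2 (0.93), HSPA4, a chaperone (0.78), MAD1L1, a spindle checkpoint protein (0.74), MORF4L1, a chromatin protein (0.74), TCFL5 (0.71) and RRP15, a ribosomal RNA processing factor (0.60). The largest falls were in OSTC (-1.50, SE 0.24, adjusted p = 0.0439), SLC2A3 (-1.40, adjusted p = 0.0261), VRK1 and IL11 (-1.29, SE 0.12, adjusted p = 0.0115). KIAA1191 and CENPK both changed by -1.0, YIPF6, a Golgi membrane protein, by -0.99 and CDKN2D, a CDK4/6 inhibitor, by -0.93. PRRG1 and ZMPSTE24, the protease that matures lamin A, both changed by -0.76. The count was 0 without HT1080 control 1, control 2 or siVRK1 1 and 1 without HT1080 siVRK1 2, and it was 84 with the HT1080 arrays fitted alone. None of the genes named for HT1080 stayed called without each of the 8 arrays. The other kept probe of CNN2 read 0.42 and that of KIAA1191 -0.87, and OSTC was not called with no filter. With an intensity trend HSPA4, RRP15 and TCFL5 were not called. The count of called genes was 66 with a replicate block, 11 with background subtracted and 109 with array weights per cell line.

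Some of the called genes were shared by the lines. Of the 94 and 29 genes called, 16 were called in both, all in the same direction. CNN2, FOXN3 and TCFL5 rose in both, where 0.0381 shared genes are expected of independent lists (Fisher's exact test, two-sided, p = 5.56e-06). CDKN2D, CENPK, IL11, KIAA1191, NEK2, OSTC, PGM2L1, PRRG1, SLC2A3, SLC44A1, VRK1, YIPF6 and ZMPSTE24 fell in both, 13 genes against 0.109 expected (Fisher's exact test, p = 6.79e-26). Other leading genes of 1 line had smaller values, or values of the other sign, in the other line. ID3 read 1.38 in MDA-MB-231 and -0.22 in HT1080, P4HA1 0.91 and -0.53, TCN1 1.09 and 0.02, JAG1 0.88 and -0.06, and PTBP3 -1.21 and -0.35, while HSPA4 read 0.08 in MDA-MB-231 and 0.78 in HT1080. Fisher's test takes genes as independent, which genes that vary together are not. The control arrays of the lines are separate, but the estimate of the spread is shared. Across all genes, which are not independent replicates, the changes correlated with Pearson's r = 0.384 and Spearman's rho = 0.292. Of the 94 genes called in MDA-MB-231, 77 had the same sign in HT1080, and of the 29 called in HT1080, 26 had the same sign in MDA-MB-231. Fitted alone, the MDA-MB-231 arrays called 0 genes, so separate fits could share none. The HT1080 arrays fitted alone called 84 genes, with all 29 genes called there by the main fit among them. The shared count was 6 without MDA-MB-231 siVRK1 1, 0 without HT1080 control 1, control 2 or siVRK1 1, 1 without HT1080 siVRK1 2, and 0 with each line fitted alone.

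**Figure D2:**
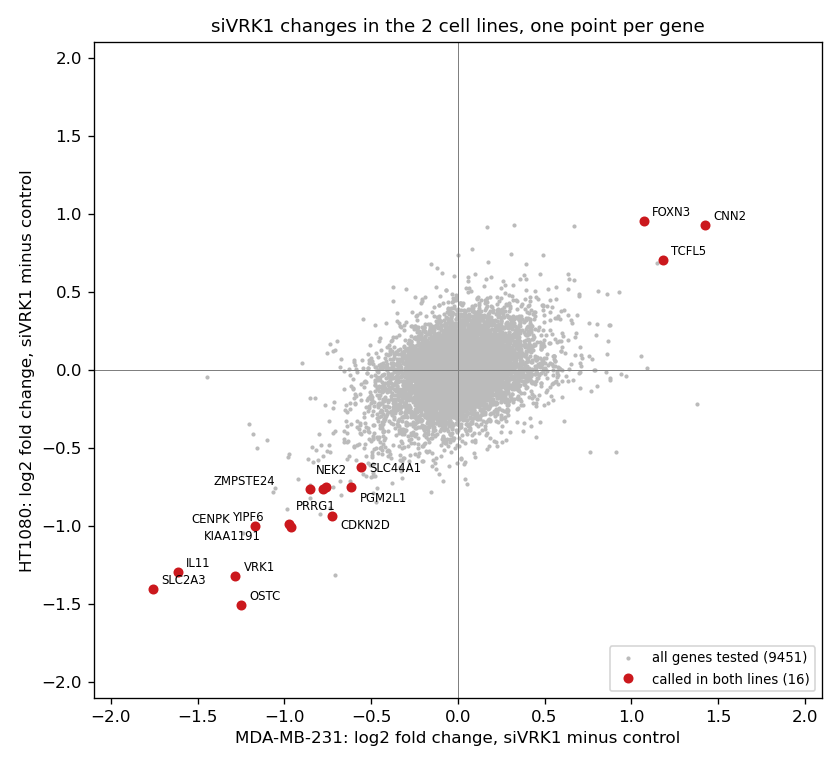
Log2 fold change after siVRK1 in MDA-MB-231 (x axis) and in HT1080 (y axis), with 1 point for each of 9451 genes and the 16 genes called in both lines in red. The red points lie in the quadrants of equal sign, 3 up and 13 down.

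Averaged over both lines, siVRK1 changed 240 genes, 91 up and 149 down, with 1471 at an unadjusted p under 0.05. CNN2 rose by 1.18 log2, FOXN3 by 1.01, TCFL5 by 0.94 and PLLP by 0.92 (adjusted p from 0.000524 to 0.00275). SNAI2, a repressor of epithelial genes, rose by 0.79 (SE 0.15, adjusted p = 0.0245). LRP8, the amylase AMY1A, MXD4, a partner of MAX, HAS3 and WBP1L rose by 0.71, 0.68, 0.66, 0.63 and 0.63. AMY1A belongs to a family of near-identical genes that 1 probe may not separate. The largest falls were in SLC2A3 (-1.58), IL11 (-1.45, SE 0.09, adjusted p = 0.000149), OSTC (-1.37), VRK1 and SFXN1 (-1.14), followed by CENPK (-1.08), KIAA1191 (-0.98), YIPF6 (-0.98), CCND1, cyclin D1 (-0.94, adjusted p = 0.00618), and SMS, spermine synthase (-0.90). CNN2, FOXN3, TCFL5, PLLP, HAS3, SLC2A3, IL11, VRK1, SFXN1, CENPK, KIAA1191 and YIPF6 stayed called without each of the 8 arrays. OSTC and WBP1L lost the call without 1, LRP8 and CCND1 without 2, AMY1A and MXD4 without 3, SMS without 4 and SNAI2 without 5 (adjusted p up to 0.143). The other kept probe read 0.56 for CNN2, 0.19 for LRP8 and -0.89 for KIAA1191. Not all of these genes were called in each line. SNAI2 was called in neither, HAS3 only in HT1080, and PLLP, LRP8, AMY1A, MXD4, WBP1L, SFXN1, CCND1 and SMS only in MDA-MB-231. In control cells HAS3 read 5.89 in MDA-MB-231 and PLLP 5.85 in HT1080, both background level. The count was 111 without MDA-MB-231 siVRK1 1, 157 without MDA-MB-231 siVRK1 2, 26 and 23 without HT1080 control 1 and 2, and 48 and 51 without HT1080 siVRK1 1 and 2. With a fold of at least 1.5 required it was 63, with a replicate block 501 and with background subtracted 116.

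Genes of G2/M and mitosis fell as a group in both lines. The median change of the 39 measured genes was -0.40 log2 in MDA-MB-231 and -0.38 in HT1080, and in each line 38 of 39 had a negative value (camera in limma, adjusted p = 2.43e-20 and 1.9e-22). With an estimated correlation the adjusted p = 0.374 in MDA-MB-231 and 0.651 in HT1080, so the group's call depends on how strongly its genes are taken to vary together. By fry the group was not called in HT1080, where 0 lists passed. NEK2, a centrosomal kinase, fell in both lines (-0.76, adjusted p = 0.0233, and -0.75, adjusted p = 0.0439), and CDC20, an activator of the anaphase-promoting complex, in MDA-MB-231 (-0.64, adjusted p = 0.0405). Single genes otherwise did not pass over all genes tested. Adjusted over the list alone, 27 genes fell in MDA-MB-231 and 22 in HT1080. BIRC5 was at -0.76 in MDA-MB-231 and TOP2A at -0.69 in HT1080, while MKI67 (0.01) and CDK1 (-0.07) stood highest in MDA-MB-231 and CENPE (0.04) and BUB1B (-0.10) in HT1080. The group remained called in both lines without each of the 8 arrays. Its difference between the lines was -0.01 log2 by the median (adjusted p = 0.777) and by the mean 0.01. It was -0.16 (adjusted p = 0.0483) without MDA-MB-231 control 1 and 0.11 (adjusted p = 0.0110) without MDA-MB-231 control 2. NEK2 lost its call without 6 of the 8 arrays in MDA-MB-231 and 4 in HT1080, and CDC20 without 7, with adjusted p up to 0.110, 0.385 and 0.183.

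On the average of the lines all 39 G2/M genes had a negative value, with a median of -0.39 log2 (adjusted p = 4.72e-28, and adjusted p = 0.601 with an estimated correlation). There 14 fell over all genes tested and 34 adjusted over the list alone. Beside NEK2 (-0.76, SE 0.08, adjusted p = 0.00271) they included the survivin gene BIRC5 (-0.64, adjusted p = 0.0276), the kinesins KIF2C (-0.61), KIF23 (-0.52), KIF20A (-0.45) and KIF11 (-0.43), the kinases AURKA (-0.58, adjusted p = 0.00941) and TTK (-0.50), and the mitotic cyclin gene CCNB2 (-0.55). CKAP2, CDCA8, CDC20, HMMR and PTTG1 changed by -0.60, -0.52, -0.50, -0.48 and -0.47. NEK2 stayed called without each of the 8 arrays, and the other 13 lost the call without at least 4 of them. KIF23 was also not called with the mean of its probes, and CDCA8 and KIF20A were not called with no filter.

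**Figure D3:**
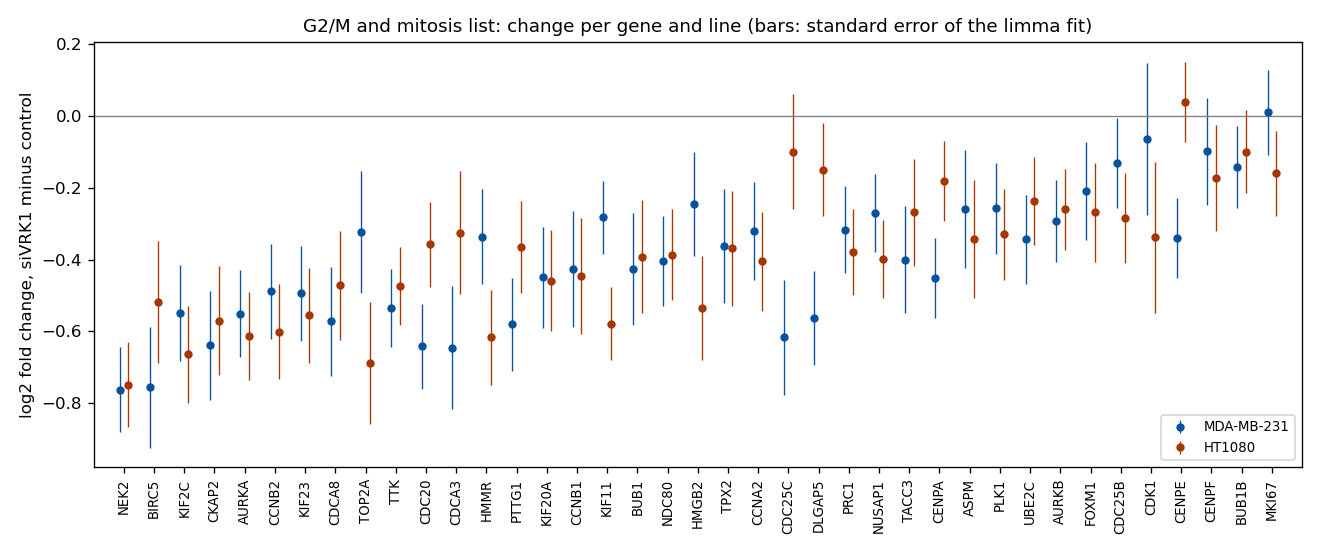
Log2 fold change after siVRK1 of each of the 39 measured G2/M and mitosis genes in MDA-MB-231 (blue) and HT1080 (red), with bars of 1 SE of the limma fit from 2 arrays per group. In each line 38 of 39 points lie below 0, from NEK2 at -0.76 to MKI67 at 0.01 in MDA-MB-231 and from NEK2 at -0.75 to CENPE at 0.04 in HT1080.

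Genes of G1/S and DNA replication had smaller median changes than the G2/M genes, and no test compared the groups. Their median over 34 measured genes was -0.14 log2 in MDA-MB-231 (27 negative, adjusted p = 0.00403) and -0.12 in HT1080 (28 negative, adjusted p = 0.0644), and -0.10 on the average of the lines (adjusted p = 0.00145). With an estimated correlation the adjusted p = 0.812, 0.833 and 0.726. PCNA, the sliding clamp of DNA polymerases, fell in MDA-MB-231 (-0.98, SE 0.16, adjusted p = 0.0276) and on the average (-0.77, adjusted p = 0.00941), where GINS2 (-0.73) and MCM10 (-0.58), both of the replication machinery, also fell. The same 3 genes made up the count adjusted over the list alone on the average, against 1 in each line. CCNE1, cyclin E1, read 0.25 in MDA-MB-231 and 0.46 in HT1080. The group's median in MDA-MB-231 was 0.02 without MDA-MB-231 control 1 (adjusted p = 0.863), and the call was lost without siVRK1 1 of that line (adjusted p = 0.0722). On the average it was lost without MDA-MB-231 control 1 (adjusted p = 0.269). PCNA lost its call without 6 of the 8 arrays in MDA-MB-231 (adjusted p up to 0.121) and 3 on the average (up to 0.0780), where GINS2 lost it without 5 and MCM10 without 6 (both up to 0.157). With the mean of its probes MCM10 was not called, and with no filter GINS2 was not.

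In MDA-MB-231 the TGF-beta/SMAD target group rose, with a median of 0.32 log2 over 11 measured genes and 10 positive (adjusted p = 0.00262, and adjusted p = 0.374 with an estimated correlation). ID3 was its 1 member called, and 4 rose adjusted over the list alone. ID1 read 0.76 (adjusted p = 0.206), ID2 0.05 and SKI -0.10. In HT1080 the group's median was 0.03 (adjusted p = 0.972), with ID1 at -0.53 and ID3 at -0.22. The group stayed called in MDA-MB-231 without each of the 8 arrays, with medians from 0.23 to 0.40.

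Further groups called in MDA-MB-231 each held at most 1 gene called over all genes tested. Extracellular matrix genes had a median of 0.05 over 24 (adjusted p = 0.0218), with COL4A1, a basement membrane collagen, up by 0.88 (adjusted p = 0.0117) and 7 up and 1 down adjusted over the list alone. Interferon-stimulated genes had a median of 0.13 over 36 (adjusted p = 0.0218), with IFI27 alone called, up by 0.55, also adjusted over the list alone. Epithelial junction and keratin genes had a median of 0.20 over 15 (adjusted p = 0.0300), with KRT7 up by 0.77 (adjusted p = 0.0172), JUP at 0.71 and 3 up adjusted over the list alone. Leukocyte markers, 4 genes measured, had a median of -0.29 (adjusted p = 0.0218), with 0 called over all genes, 2 down adjusted over the list alone, and LAPTM5 at -0.61 and CD68 at -0.31. The VRK kinases (median -0.20, adjusted p = 0.0452) held only VRK1, the siRNA's own target, as a called gene. Their call is therefore no evidence beyond the knockdown itself. With an estimated correlation the adjusted p = 0.679 for the interferon group and 0.374 for the other 4. The matrix group lost its call without MDA-MB-231 control 2 (adjusted p = 0.0935) or siVRK1 1 (0.186), the interferon group without the same arrays (0.368 and 0.413), the epithelial group without control 1 (0.299) or siVRK1 2 (0.206), and the leukocyte group without control 1 (0.330) or siVRK1 1 (0.0722). The VRK kinases kept theirs only without MDA-MB-231 siVRK1 2, with adjusted p up to 0.0942. With no filter the epithelial and leukocyte groups were not called, and with the mean of a gene's probes the leukocyte group and the VRK kinases were not. With an intensity trend the VRK kinases and IFI27 were not called. Of the single genes, IFI27 lost its call without each of the 8 arrays, KRT7 without 6 and COL4A1 without 3 (adjusted p up to 0.153, 0.0898 and 0.0595).

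Genes of the ER stress and amino acid response stood lower in MDA-MB-231, but their median depended on which array was left out. Their median was -0.27 log2 over 32 genes, with 28 negative (adjusted p = 0.0144), 0 called over all genes and 0 adjusted over the list alone by limma. ASNS, asparagine synthetase, read -0.72 and HSPA5, the ER chaperone BiP, -0.71, with MTHFD2 at 0.42. The estimated correlation between these genes was 0.862, and the adjusted p = 0.812 with an estimated correlation. The median was 0.18 (adjusted p = 0.0103) without MDA-MB-231 control 2, -0.66 without MDA-MB-231 control 1 and 0.00339 (adjusted p = 0.839) without MDA-MB-231 siVRK1 1. Same-numbered arrays of MDA-MB-231 varied together (r = 0.485 over all genes tested). Leaving out arrays one by one cannot tell such a shared shift from a single deviating array. The group was not called with the 75th percentile filter. In HT1080 its median was -0.08 (adjusted p = 0.685).

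Calls of single genes that changed differently in the lines depended on the model. The count was 0 by limma with group means alone, with 582 genes at an unadjusted p under 0.05 where 473 are expected by chance. CCNA1 came nearest (difference 1.40 log2, SE 0.17, adjusted p = 0.0751). It changed by -1.44 in MDA-MB-231, but it read 5.83 in HT1080 control cells, background level, so no fall could be measured there. MARCHF3 (0.91), LRRC20 (0.86), GTF2E1 (0.88) and SP140 (0.77, with other kept probes at 0.45 and 0.01) had the next smallest p among genes whose siVRK1 change was more positive in HT1080. P4HA1 (-1.44, SE 0.24, adjusted p = 0.349), COL4A1 (-0.93), KRT7 (-0.90), SHROOM3 (-0.90) and TNFSF10 (-0.86) had the smallest p in the other direction. KRT7 and TNFSF10 also lay at background level in HT1080, at 5.96 and 5.62. The count was 1 without MDA-MB-231 control 1, 1 without MDA-MB-231 siVRK1 2 and 1 with array weights per cell line (CCNA1). With a replicate block it was 3, CCNA1 and P4HA1 among them (adjusted p = 0.0261 for both).

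The control-treated lines differed in 5074 genes, 53.7% of those tested, with 2472 higher in HT1080 and 2602 higher in MDA-MB-231. The cancer-testis genes GAGE4, CTAG2, CT55 and GAGE7 were higher in HT1080 by 7.32, 5.75, 5.23 and 4.76 log2, as were HSD11B1, which regenerates cortisol (5.63), JAM3, a junctional adhesion molecule (5.34), CLEC11A (5.30), TMEM200A (5.20) and HS3ST3A1, a heparan sulfate sulfotransferase (5.07). The GAGE genes are near-identical copies that 1 probe may not separate. Other kept probes read lower for CTAG2 (0.88) and HSD11B1 and, among the genes higher in MDA-MB-231, COXFA4L3 (-1.74), so the size for these genes depends on the probe. In MDA-MB-231, IGFBP4, an IGF-binding protein (-7.00, SE 0.13), S100A4 (-6.80), MARCKS (-5.40), VAMP8 (-5.35), keratin KRT19 (-5.29), the cancer-testis gene SPANXC (-5.18), CYBA (-5.17), PLAAT4 (-5.15), PLIN2, a lipid droplet protein (-4.82), and COXFA4L3 (-4.80) were higher, where a negative value means lower in HT1080. Adjusted p was at most 2.8e-07 for these genes, and for all but S100A4 the lower line lay near background level, so the true ratios may be larger. VRK1 itself differed by 0.09 log2 (adjusted p = 0.676).

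Between the control-treated lines 6 of 33 gene groups were called by camera, which sets a group against the other genes. By fry, which tests the group by itself, 19 were called, so a group not listed here may still differ. Epithelial junction and keratin genes had a median of -1.42 log2 in HT1080 relative to MDA-MB-231, with 12 of 15 lower, 13 adjusted over the list alone (adjusted p = 2.38e-06), among them KRT19, SPINT2 (-4.34) and KRT7 (-3.29). Interferon-stimulated genes were also lower in HT1080 (median -0.81, 25 of 36 lower and 3 higher, or 26 and 3 adjusted over the list alone, adjusted p = 6.68e-07), among them IFI27 (-4.62), HERC5 (-3.24) and MX1 (-3.22), while TRIM22 was higher. Targets of p53 were higher in HT1080 (median 0.89, 16 of 21 higher and 1 lower, or 17 and 1 adjusted over the list alone, adjusted p = 0.000556), among them GDF15 (3.56), SESN1 (1.71) and XPC (1.49). Hypoxia and glycolysis genes were lower (median -0.39, 17 of 33 lower and 1 higher by either count, adjusted p = 0.00456), among them ADM (-4.77), and cytosolic ribosomal protein genes higher (median 0.28, 20 of 44 higher and 2 lower, or 19 and 2 adjusted over the list alone, adjusted p = 0.00518), among them RPL14 (1.74). G2/M genes were lower (median -0.26, 16 of 39 lower and 1 higher, or 15 and 1 adjusted over the list alone, adjusted p = 0.0478). With an estimated correlation the adjusted p = 0.170 for the epithelial group, 0.346 for the interferon and ribosomal groups, 0.187 for p53 targets, 0.762 for hypoxia and 0.924 for G2/M.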

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

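The tests of the overlap of calls, of their direction, of the siRNA sequence, of the G2/M spread in HT1080 alone, of single arrays in each line and of correlated list members were chosen only after the result was seen.

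The fall of the G2/M genes, -0.40 log2 in MDA-MB-231 and -0.38 in HT1080 by the median, has several possible causes. It may reflect fewer dividing cells after loss of VRK1, or other targets of the 1 siRNA sequence. It may also reflect variation between arrays shared by these genes, a trend with signal level, or a single array. Neither line's median was reached by any of 10000 random lists matched on mean level (percentile 0, lowest random medians -0.14 and -0.12), which argues against a trend with signal level. In HT1080 the median was at most -0.356 without each array of that line, which argues against a single array carrying the fall there, and the smallest difference of the list mean between control and siVRK1 arrays, 0.370, was 14.0 times the largest difference between replicates. In MDA-MB-231 it was 0.201 against 0.243 between the control arrays, a ratio of 0.826, and without each array of that line the median ran from -0.54 to -0.286, with a spread of 0.176. Array-to-array variation shared by the mitotic genes therefore stays open there, and so does a single array carrying the fall, since the arrays are too few. A lower share of dividing cells was not measured and stays a hypothesis. With 1 siRNA sequence, an effect on the G2/M genes through other transcripts cannot be told apart from one through VRK1, in either line.

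The 16 genes called in both lines may be genes that depend on VRK1, chance, a spread estimated too small in both comparisons, or other targets of the 1 siRNA sequence. Fisher's exact p was at most 5.56e-06 in either direction, which argues against a chance overlap of lists of independent genes, but not of genes that vary together. The 15 genes other than VRK1 moved in the same direction in both lines. All 29 genes called in HT1080 stayed called with that line's arrays fitted alone, so these calls did not need the pooled spread. With the MDA-MB-231 arrays fitted alone 0 genes were called. Genes that vary together are not separate trials, so a small shared estimate of the spread stays open. Of the 16, 13 fell, VRK1 included, and with 1 siRNA sequence its effect through other transcripts and its effect through VRK1 cannot be told apart. A second sequence and the transcript sequences were not analysed here.

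Gene groups whose change differed between the lines by camera in limma were the interferon-stimulated genes (median difference HT1080 minus MDA-MB-231 -0.188), the NF-kB targets and inflammatory cytokines (0.185), the epithelial junction and keratin genes (-0.119), the extracellular matrix genes (-0.195), the integrins and focal adhesion genes (-0.194) and the TGF-beta/SMAD targets (-0.199), with adjusted p from 0.00025 to 0.00951 and 0 groups called by fry. Members at background level in 1 line could blunt a change there. In 6 of 6 groups the members above the filter level in the control arrays of both lines kept at least 50% of the difference. These were 5 of 15 epithelial, 8 of 11 TGF-beta/SMAD, 12 of 17 NF-kB, 17 of 24 matrix, 22 of 36 interferon and 23 of 28 integrin genes. The filter level, 6.08 log2, lies within the range called background level here, so members just above it may still be blunted. Members that vary together between replicate arrays remain a candidate explanation, since with an estimated correlation the smallest adjusted p was 0.245. The interferon group lost its call without MDA-MB-231 control 2 (adjusted p = 0.0945), MDA-MB-231 siVRK1 1 (0.156) or HT1080 control 2 (0.0551), the NF-kB group without MDA-MB-231 control 2 (median -0.03, 0.652) or HT1080 control 1 (0.0722), the epithelial group without MDA-MB-231 control 1 (0.183) or siVRK1 2 (0.144), and the integrin group without HT1080 control 1 (0.0841). The TGF-beta/SMAD group lost its call with no filter on dim probes and the NF-kB group with the 75th percentile filter. A difference in how the lines respond to siVRK1 stays open.

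Among the 1103 probes without a gene name, 16 were called on the average of the lines, 7 up and 9 down.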

How the results depend on the processing

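Counts of called genes moved more than directions. With only the groups compared, the count was 0 in MDA-MB-231, 84 in HT1080 and 0 shared, and VRK1 in MDA-MB-231 was -1.28 log2 (adjusted p = 0.292). With a replicate block, counts were 297, 66, 501 on the average, 3 for the difference and 38 shared; same-numbered replicates correlated with r = 0.485 in MDA-MB-231 and -0.0485 in HT1080. With background subtracted they were 8, 11, 116 and 5 shared, and VRK1 changed by -1.81 (adjusted p = 0.0510) and -1.80 (adjusted p = 0.0513). With array weights per cell line they were 51, 109 and 1 for the difference. A fold of at least 1.5 gave 63 on the average and 2991 between lines, and the 75th percentile filter 3136 between lines. Without each array in turn, counts ran from 10 to 108 in MDA-MB-231, 0 to 39 in HT1080, 23 to 273 on the average, 0 to 1 for the difference and 0 to 18 shared, and VRK1 from -1.54 to -1.03 and from -1.35 to -1.29. The share of calls that rose, 47.9% in MDA-MB-231, was 62.5% without siVRK1 1, 26.5% without siVRK1 2 and 37.5% with background subtracted, and on the average, 37.9%, it was 15 up against 48 down at a fold of at least 1.5 and 26.1% without MDA-MB-231 siVRK1 2 or HT1080 control 2. Gene lists called were 0 in all comparisons of camera with an estimated correlation. With fry they were 3 in MDA-MB-231, 0 in HT1080, 4 on the average and 0 for the difference. HT1080 had 3 with no filter or an intensity trend, and the average 4 with no filter or a replicate block. Without each array lists called ran from 4 to 10, 1 to 3, 2 to 7 and 4 to 11. G1/S in MDA-MB-231 ran from -0.29 to 0.0150 and its difference from -0.14 to 0.20, the G2/M difference from -0.16 to 0.11, ER stress in MDA-MB-231 from -0.66 to 0.18 and its difference from -0.27 to 0.60, the extremes without MDA-MB-231 control 1 or 2. The correlation across genes was 0.303 to 0.368 without each array. Of 2253 alternative values for 115 called results of named genes, 1790 kept the call, 463 lost it and 0 reversed. Of 190 for the 10 uncalled differences between lines, 186 stayed uncalled and 4 gained a call. The called results include genes that differed between the control-treated lines, which kept the call in every alternative. The siVRK1 calls therefore kept a smaller share. Quantile normalization and median centring, of columns that already shared nearly the same distribution, changed no call of a named gene. The calls in MDA-MB-231 rest on a spread pooled with the quieter HT1080 arrays, and the cause of that difference was not tested. Dim probes' signal over background limits their changes. Different log2 offsets were not compared, since the deposited values were log2 already. The background subtraction used its fixed offset alone, so how far its results depend on that offset is not known.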

Other observations

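The count of other splits was planned, and the genes singled out here as called members of lists were chosen after their values were seen.

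Several called genes sat in groups that camera did not call in either line or on the average. Among G1 cyclins, CDKs and CDK inhibitors (median 0.05 log2 in MDA-MB-231 and -0.05 in HT1080, 16 genes), CDKN2D fell in both lines (-0.73 and -0.93) and cyclin D1, CCND1, in MDA-MB-231 (-0.99, limma adjusted p = 0.0363) but not past the threshold in HT1080 (-0.89, adjusted p = 0.0875), where MYC read 0.92 (adjusted p = 0.106). Adjusted over the list alone, 2 fell in each line and 1 rose in HT1080, and the mean in MDA-MB-231, -0.08, had the other sign than the median. Among matrix proteases and their inhibitors (-0.01 and -0.10, 19 genes) PLAU, the urokinase, fell in MDA-MB-231 (-1.10, adjusted p = 0.0144) and read -0.45 in HT1080, and PLAUR, its receptor, fell on the average (-0.45, adjusted p = 0.0203). In the NF-kB group (-0.12 and 0.15, 17 genes), called only for the difference between the lines, IL11 alone was called, in both lines, with IL6 at 0.58 in MDA-MB-231 and IL1B at 0.53 in HT1080. Among hypoxia and glycolysis genes (-0.01 and -0.02, 33 genes) SLC2A3 fell in both lines and P4HA1 rose in MDA-MB-231. Adjusted over the list alone, 1 protease gene rose and 2 fell in MDA-MB-231 with 1 fall in HT1080, and 3 hypoxia genes rose and 1 fell in MDA-MB-231 against 1 and 1 in HT1080. CCND1 and PLAU lost the call in MDA-MB-231 without 7 and 3 of the 8 arrays, with adjusted p up to 0.101 and 0.0620, PLAUR lost it on the average without 5 (up to 0.122), and CDKN2D stayed called on the average without each of them but lost its call in MDA-MB-231 without 7 (up to 0.124).

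Mesenchymal regulators (0.07 and -0.01, 19 genes) held CDH11, up in MDA-MB-231 (0.54, adjusted p = 0.0475), and SNAI2, up on the average. By fry, unlike camera, this group was called in MDA-MB-231 and on the average (adjusted p = 0.00926 and 0.0138). The YAP/TAZ targets (0.09 and 0.12, 20 genes) held F3, tissue factor, up in MDA-MB-231 (0.69, adjusted p = 0.0482). HSPA4 was the called member of the heat shock group (-0.07 and -0.02, 15 genes). On the average H3-3B, a histone H3.3 gene, fell by 0.70 (adjusted p = 0.00785) among the histone genes (0.01 and -0.06, 17 genes), the pro-apoptotic gene PMAIP1 fell by 0.48 among apoptosis regulators (0.00 and -0.07, 22 genes), and the Golgi genes ARF1 and GBF1 rose by 0.45 and 0.36 (group 0.00 and -0.06, 21 genes). CDH11 lost its call without each of the 8 arrays, F3 in MDA-MB-231 without 7, and ARF1 and GBF1 without 7, with adjusted p up to 0.165, 0.179, 0.199 and 0.149, and PMAIP1 without 5 and H3-3B without 3 (up to 0.147 and 0.0694). ARF1 was also not called with the mean of its probes or with no filter, nor were F3 and, among the genes above, CCND1 in MDA-MB-231 with no filter. With an intensity trend CDH11, GBF1 and HSPA4 were not called. Adjusted over the list alone, 2 mesenchymal genes rose in MDA-MB-231 and 1 in HT1080, 3 YAP/TAZ targets rose and 2 fell in MDA-MB-231, 2 histone genes rose and 1 fell in MDA-MB-231 with 1 fall in HT1080, and 2 Golgi genes rose in MDA-MB-231.

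The remaining groups had 0 called genes in limma in either line and no call by camera in the groups' changes in HT1080 or on the average, and are given as medians in MDA-MB-231 and HT1080. VRK1 substrates and nuclear envelope partners stood at -0.13 and -0.06, with LMNB1, lamin B1, at -0.49 and -0.35. Targets of p53 stood at -0.02 and 0.03, DNA damage repair genes at -0.07 and -0.09 and immediate early genes at 0.01 and -0.01. Cholesterol synthesis genes stood at -0.11 and 0.02, with HMGCS1 at -1.06 (adjusted p = 0.165) and -0.78, and fatty acid synthesis genes at 0.14 and 0.02. Oxidative phosphorylation genes stood at 0.04 and 0.09, ribosomal protein genes at 0.00 and 0.05, autophagy and lysosome genes at 0.01 and 0.03, senescence secretory factors at 0.13 and 0.06 and small RNA pathway genes at 0.07 and 0.02. Endothelial markers stood at -0.03 and 0.05, neural markers at 0.07 and -0.06 and, in HT1080, leukocyte markers at -0.14. Integrins, called by camera for the difference between the lines alone, stood at 0.07 and -0.09. Adjusted over the list alone, 2 immediate early genes fell and 2 integrin genes rose in MDA-MB-231, and 2 senescence factors rose in HT1080. Median and mean differed in sign, both near 0, for p53 targets, immediate early, ribosomal, apoptosis and neural genes in MDA-MB-231 and for mesenchymal, cholesterol and heat shock genes in HT1080. The direction of the camera test differed from the sign of the median for G1 cyclins, immediate early, ribosomal, apoptosis and matrix protease genes in MDA-MB-231 and for VRK kinases, mesenchymal, heat shock, hypoxia and Golgi genes in HT1080.

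The arrays allow 18 splits that keep 2 arrays of each line on either side, the real one included, too few for a share under 0.05. With cell line as a term, the real split called 232 genes and the highest of the others 0, so 1 split, the real one, gave as many.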
